A study of Mus musculus with 8 samples.

How the data were processed

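The measurements are 8 3' end RNA sequencing libraries (QuantSeq, which reads a short stretch near the polyadenylated end of each transcript, so that a count is close to 1 per transcript whatever its length) from liver and uterus of female CD-1 mice, an outbred stock. The animals had been ovariectomized, which removes the main source of estrogen. Per the labels' protocols, they received bisphenol A (BPA, a plastics monomer that can bind estrogen receptors) at 200 mg/kg/day, Korean red ginseng (KRG) at 1.2 g/kg/day, both, or neither, by mouth for 7 days, and 500 ng of total RNA entered each library. Each tissue has 4 libraries, 1 per treatment. The labels do not say whether a library is 1 animal or a pool, nor whether liver and uterus came from the same animals.

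The deposited files hold raw whole-number counts per gene, 1 file per library, over 23282 gene rows named by symbol, of which 44 repeat a symbol and were kept as separate rows. The submitters' processing notes name Bowtie2, edgeR and the mm10 build, without versions or roles. The counter, the treatment of reads with several matches and the use of strand are not given in the sources used here. Genes with near-identical copies (the Mup, amylase, hemoglobin, Sult2a and Il11ra2 families among them) and genes that overlap a neighbour are therefore reported as uncertain. Library totals ran from 12372073 to 15290950 counts. Rn45s, the ribosomal RNA precursor, took between 8.30% and 12.4% of each library and was left in the totals.

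Counts were scaled within each tissue by the trimmed mean of M values (edgeR 4.0.16 in R 4.3.3) and are given as CPM, counts scaled to a common library size. Ratios are on the log2(CPM + 1) scale, which understates the change of low genes, and folds given with an interval are ratios of CPM without the pseudocount. Genes with a mean of at least 10 CPM over the 4 libraries of a tissue were used, 6705 in liver and 9198 in uterus. With 1 library per group there is no replicate error, and no comparison of 2 libraries was tested. The 95% intervals are exact Clopper-Pearson intervals of the ratio given the sum of both counts. They address counting error only, and they compare libraries, not treatments. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Where a count was 0, the fold is a lower bound against 3 counts in that library.

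The comparisons were BPA against control, KRG against control, both against BPA, both against control and both against KRG, each with the number of genes at least 2-fold higher or lower. BPA and KRG each have a second pair of libraries that shares no library with the first, and genes at least 2-fold in the same direction in both pairs were counted beside the number that independent lists would share (n1 × n2 / N). Genes at least 2-fold different with BPA were asked whether the library given both lay closer to control than to BPA, and the library given KRG alone was set beside it, since the BPA and control libraries enter both sides. A simulation of 20 draws in which all 4 libraries of a tissue shared 1 mean was set beside these values. Its dispersion (0.0444 in liver, 0.0472 in uterus) came from the additive model of the same 4 libraries, described below, which takes any interaction as error. Genes were drawn independently at that dispersion. Its counts therefore do not show what libraries without an effect would give. Gene lists (51, of pathways, sample quality and cell type markers) are given by their median and its percentile among 10000 random lists matched on mean expression in 20 bins. The percentile describes these libraries and is not a test, and the lists printed were chosen after their values were seen, while 16 of the 35 lists measured in liver and 23 of the 33 in uterus lay outside percentiles 2.5 to 97.5 for BPA against control.

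The gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said. Named genes were the 10 genes higher and 10 lower with the largest smaller log2 ratio over both pairs of a factor, the 5 higher and 5 lower with the largest ratio in BPA against control, KRG against control and both against BPA, the 4 members with the largest ratio of each list outside percentiles 2.5 to 97.5, and always Esr1, Pgr, Ltf, Cyp2b10, Cyp3a11 and Cyp7a1 where they passed the filter. Yae1d1, Padi1, Foxa2 and, in liver, Cwc22 and the Il11ra2 cluster fall outside it and were chosen after their values were seen, as were others where the text says so. Part of the genes that the rule names is described, and a result in uterus is not reported here. Coordinates are from GENCODE M21, which is on the same build as mm10.

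Alternatives were DESeq2 size factors, total count scaling, a mean of at least 1 CPM, no expression filter, pseudocounts of 0.25 and 5 CPM, and an additive model of BPA and KRG over the 4 libraries of a tissue with edgeR's quasi-likelihood test or DESeq2 1.42.0 (Benjamini-Hochberg adjusted p under 0.05), which has 1 residual degree of freedom and takes any interaction as error. Counts without genes at least 10-fold higher in the other tissue and without cell type marker genes were added after the data were seen. The methods were tested on simulated counts. With 200 genes changed 4-fold, the rule of 2-fold in both pairs recovered 168 of 200 in liver and 178 of 200 in uterus at the measured dispersion, with 1 and 2 other genes called among 6633 and 9125. In that simulation genes were drawn independently at 1 common dispersion, without interaction, tissue of another kind or shared reads. The few other genes called follow from that setting and do not give the rule's error in the measured libraries. The 95% intervals held the true ratio for 94.9% of 4000 simulated liver ratios and 95.1% of 4000 uterus ratios. Those counts were Poisson draws without the measured dispersion, so this coverage follows from the method. It does not hold for spread between libraries. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.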

Results

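Gene expression was measured by 3' end RNA sequencing in liver and uterus of ovariectomized CD-1 mice in 4 groups, control (neither treatment), BPA, KRG, or BPA with KRG. Each of the 8 groups holds 1 library. Totals were 15290950, 12971825, 14591384 and 12372073 counts for the control, BPA, KRG and combined liver libraries, and 13382974, 13721914, 12990417 and 14797515 for the uterus libraries in the same order. Values are therefore levels in single libraries, with no replicate check. The series asks whether ginseng changes the influence of BPA on these tissues. Where 4 CPM values follow a gene below, they stand in the order control, BPA, KRG and both.

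The libraries of uterus fell into a pair with BPA and a pair without it. The standard deviation of log2 ratios over 9198 genes was 0.45 between the BPA and combined libraries and 0.48 between control and KRG, against 0.61 to 0.93 between libraries that differ in BPA. Liver showed no such pairing. Over 6705 genes the BPA liver library stood farthest from the other 3, at 0.52 to 0.54, and the other 3 lay 0.40 to 0.45 apart.

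In liver, BPA against control gave 108 genes at least 2-fold higher and 139 lower, and 82 higher and 205 lower with total count scaling. Libraries simulated with 1 mean gave 140.25 genes 2-fold apart on average in liver. Of the glutathione transferases, enzymes that conjugate electrophiles, Gstm1, Gstm3 and Gsta2 were higher in both libraries given BPA. Gstm1 stood at 465, 1762, 536 and 1281 CPM, 3.79-fold (95% counting interval 3.69 to 3.89) higher than control with BPA and 2.39-fold higher with both against KRG. Gstm3 (42.1, 152, 37.6 and 104 CPM) and Gsta2 (9.09, 89.2, 11.7 and 25.9 CPM) were also higher in both. Gstm4 stood at 21.1, 61.3, 37.8 and 49.7 CPM. The phase II conjugation list had 8 of 33 measured members at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.20, percentile 98), and the NRF2 target list had 2 of 15 measured members at least 2-fold higher and 2 at least 2-fold lower (median log2 ratio 0.32, percentile 99.9), with Nqo1 and Ephx1 higher and Osgin1 and Txn1 lower. Cyp2b10, a target of the xenobiotic receptor CAR, was 2.32-fold (95% counting interval 2.06 to 2.62) higher with BPA and 1.74-fold higher with both against KRG, while the list of CAR and PXR targets had a median log2 ratio -0.11, percentile 0.62, which came inside the middle 95% (-0.08) with a filter of 1 CPM. With both against KRG its median was 0.47, and with KRG against control -0.37. Cyp3a11 stood at 1335, 959, 1035 and 934 CPM. The other genes at least 2-fold higher in both pairs were Gadd45g, Ces1g, Sgk2, Slc3a1, Orm3, Igfbp1, Fpgs, Yae1d1 and Saa2.

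Genes with female-biased liver expression were lower in the BPA liver library: 1 of 19 measured members at least 2-fold higher and 11 at least 2-fold lower (median log2 ratio -1.37, percentile 0). A1bg was 6.96-fold lower (6.7 to 7.24), Cyp2a4 6.35-fold lower, Sult2a2 5.42-fold lower and Cyp2c69 3.89-fold lower. Of these, A1bg was also lower with both against KRG, by 2.55-fold, and the list median of that pair was 0.43. The glycogen regulators stood higher in the BPA library, Ppp1r3g at 16.6, 69.2, 45.4 and 38.8 CPM and Ppp1r3c at 42.6, 119, 57.8 and 55.3 CPM, within a list with 3 of 20 measured members at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.54, percentile 100). With both against KRG that list went the other way (median log2 ratio -0.26, percentile 0). Esr1, the estrogen receptor, stood at 24.3, 12.6, 17.2 and 23.5 CPM and Cyp7a1, the first enzyme of bile acid synthesis, at 106, 122, 142 and 99.7 CPM.

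Markers of other tissues moved with these genes. Acinar pancreas genes were high in the BPA liver library: Amy2a5 was at 0 counts in control and at 457 CPM with BPA, at least 2377-fold higher, and stood at 1.65 and 1.24 CPM in the other 2 libraries. The acinar list had 9 of 9 measured members at least 2-fold higher and 0 at least 2-fold lower, Pnlip, Prss2 and Cela3b among the former. Skeletal muscle genes were present in the control and KRG livers and nearly absent from both livers given BPA, with Tnnc2 at 45.6, 0.246, 114 and 0 CPM and Acta1 at 42.5, 0.246, 117 and 0.155 CPM (0 of 5 measured members at least 2-fold higher and 5 lower, median log2 ratio -4.29, percentile 0). With KRG against control the muscle median was 1.44. The muscle genes Tnnc2, Acta1, Tnni2, Mb, Ckm, Tcap and Mylpf were among the genes lower in both BPA pairs, with G0s2 and Tsku. Erythroid genes were higher with BPA (4 of 7 measured members at least 2-fold higher and 0 lower, median log2 ratio 1.06, percentile 100), with Hba-a1 at 2014, 4595, 2966 and 981 CPM, and lower with both against KRG (median -1.69). Of cells resident in liver, the medians of hepatic stellate markers (0 of 7 measured members at least 2-fold higher and 1 lower, median log2 ratio -0.46, percentile 0.35) and macrophage markers (0 of 10 measured members at least 2-fold higher and 0 lower, median log2 ratio -0.28, percentile 1.13) lay below 0 with BPA. With both against KRG these medians were -0.13 and 0.48.

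Over both BPA pairs in liver, 12 genes were higher and 17 lower, against 1.43 and 1.91 for independent lists, and 38 genes were 2-fold in opposite directions, against 3.33. The BPA ratios with and without ginseng had a Pearson correlation across genes of 0.07, where genes are not independent replicates. In the additive model, edgeR's quasi-likelihood test called 0 genes higher and 0 lower for BPA at an adjusted p under 0.05 (359 genes at an unadjusted p under 0.05), and DESeq2 called 12 higher and 14 lower.

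**Figure D1:**
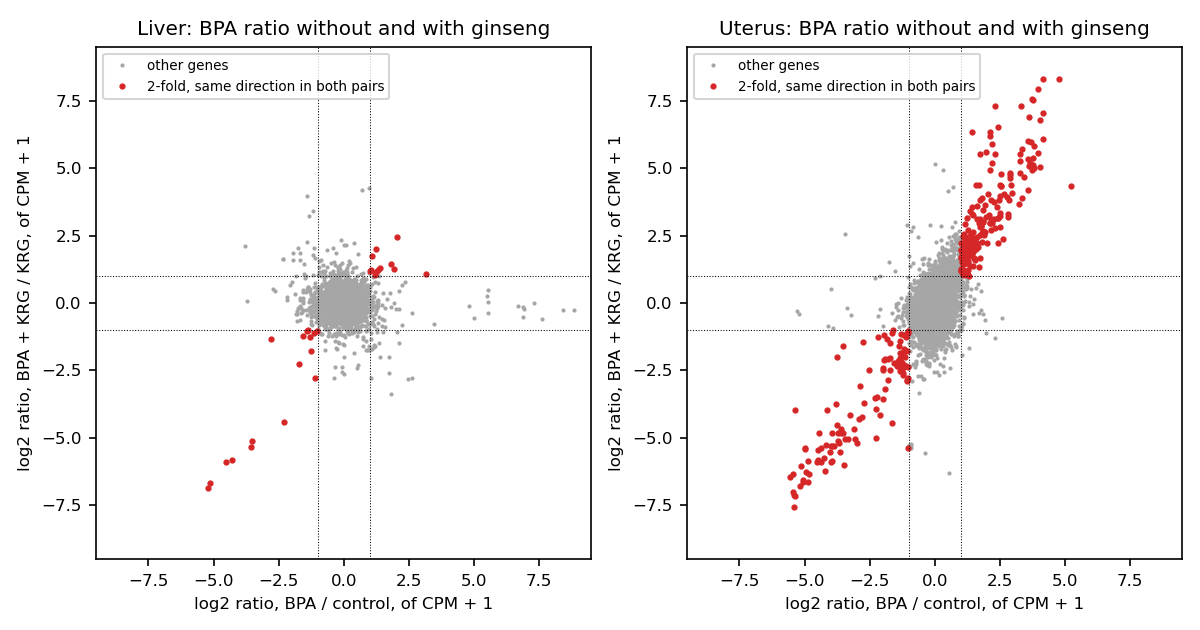
Each point is a gene, with the log2 ratio of BPA to control on the x axis and of the combined library to KRG on the y axis (log2 of CPM + 1), in liver (left, 6705 genes) and uterus (right, 9198 genes). Red points are at least 2-fold in the same direction in both pairs, 29 in liver and 314 in uterus, and dotted lines mark 2-fold.

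Ginseng alone in liver gave 75 genes at least 2-fold higher and 83 lower, beside the 140.25 genes that simulated libraries with 1 mean gave on average. The dispersion of that simulation came from these same liver libraries, so the nearness of the counts is in part built in. Serum amyloid A genes, which encode acute phase proteins made by hepatocytes, were among those with the largest ratios. Saa1 stood at 44.7, 70.5, 838 and 1076 CPM, 18.8-fold (95% counting interval 17.4 to 20.3) higher with KRG than in control and 15.3-fold higher with both than with BPA, and Saa2 stood at 21.1, 43.5, 202 and 463 CPM. The acute phase list had 6 of 27 measured members at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.20, percentile 99.97), with Lcn2 (3.27, 13.6, 30.4 and 39.3 CPM) and Mt2 (977, 2446, 3337 and 3375 CPM) among them. Its median was also above 0 with BPA (0.34). Neutrophil genes S100a8 (5.12, 7.13, 11 and 55 CPM) and S100a9 (1.99, 2.21, 6.46 and 31.8 CPM) were higher in both libraries given KRG, S100a8 mostly in the combined one. Cholesterol synthesis genes were lower with KRG: 0 of 25 measured members at least 2-fold higher and 6 at least 2-fold lower (median log2 ratio -0.74, percentile 0). Sqle was 4.31-fold lower (3.78 to 4.92), Idi1 4.37-fold lower and Mvd 3.57-fold lower. With both against BPA the list median was -0.27. Fatty acid synthesis had a median of -0.34 with 0 of 20 measured members at least 2-fold higher and 1 at least 2-fold lower. Medians of marker lists lay above 0 in the same comparison, for erythroid (0 of 7 measured members at least 2-fold higher and 0 lower, median log2 ratio 0.66, percentile 100), skeletal muscle (5 of 5 measured members at least 2-fold higher and 0 lower, median log2 ratio 1.44, percentile 99.97), acinar pancreas (2 of 9 measured members at least 2-fold higher and 0 lower, median log2 ratio 0.35, percentile 99) and neutrophil markers (2 of 3 measured members at least 2-fold higher and 0 lower, median log2 ratio 1.32, percentile 99.98). With a pseudocount of 5 CPM the acinar median came inside the middle 95%, at 0.10. The ribosomal protein list, fixed as a measure of sample quality, had 0 of 60 measured members at least 2-fold higher and 0 lower (median log2 ratio 0.19, percentile 100).

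Male-biased liver genes were lower in both livers given KRG, with 0 of 17 measured members at least 2-fold higher and 4 at least 2-fold lower for KRG against control and 0 of 17 measured members at least 2-fold higher and 11 at least 2-fold lower for both against BPA. The 17 genes of the major urinary protein (Mup) family summed to 5146, 5845, 1399.9 and 1328 CPM, and 14 of them were at least 2-fold lower in both KRG pairs, a count that shared reads between the copies make uncertain. Hsd3b5, a steroid dehydrogenase of male liver, stood at 27.3, 25.9, 4.74 and 1.55 CPM. The male-biased list had a median log2 ratio of -0.33 with KRG against control and -1.06 with both against BPA. Over both KRG pairs 10 genes were higher and 28 lower, against 1.05 and 1.45 for independent lists, 35 genes were in opposite directions, against 2.47, and the correlation across genes was -0.07. The 14 Mup genes and the Il11ra2 cluster named below make up most of the 28. These are copies or neighbours that may share reads, so the 28 are not separate observations. The number for independent lists takes no account of this. Of the 10 higher genes, Ccl27a, Gm4794, Snrnp25, Eif4ebp2, Sult3a1 and Dpy19l3 stood beside Lcn2, S100a9, Saa1 and Saa2. The 28 lower genes included Il11ra2, Gm13305, Gm13306, Gm2002 and Ccl27b of chromosome 4, with Il11ra2 at 204, 186, 91.4 and 84.6 CPM and Gm13305 at 203, 185, 90 and 83.8 CPM, nearly equal, and Ccl27b at 63.3, 69.5, 27.4 and 28.3 CPM, and Cyp7b1, Igfbp2 and Cwc22. The additive model called 0 genes for KRG by edgeR (219 at an unadjusted p under 0.05), and 14 higher and 35 lower by DESeq2.

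Adding ginseng to BPA in liver gave 94 genes at least 2-fold higher and 117 lower than BPA alone, beside the 140.25 of simulated libraries with 1 mean. Female-biased genes were higher (15 of 19 measured members at least 2-fold higher and 1 at least 2-fold lower, median log2 ratio 1.39, percentile 100). Sult2a2 was 14.8-fold (95% counting interval 12.5 to 17.8) higher and Cyp3a44 19.7-fold higher, both above their control levels, whereas A1bg at 655 CPM stayed below control at 1663 CPM. The list of peroxisome proliferator targets had 1 of 26 measured members at least 2-fold higher and 4 lower, with Cyp4a14 at 886, 1809, 1246 and 179 CPM and Cyp4a10 at 159, 158, 139 and 34.3 CPM (median log2 ratio -0.33, percentile 0). The macrophage list had 3 of 10 measured members at least 2-fold higher and 0 lower (median log2 ratio 0.69, percentile 100), led by Marco at 12.7, 10.2, 17.9 and 66.8 CPM. The heat shock list had 0 of 13 measured members at least 2-fold higher and 1 lower, Hspa1b at 13.8, 13.4, 22 and 2.94 CPM (median log2 ratio -0.44, percentile 0.01). With KRG against control the medians of these 3 lists were 0.02, 0.05 and 0.17, and that of the female-biased list was -0.12. The pancreatic genes and the erythroid genes were lower (-5.25 and -2.10 in median log2 ratio), and neutrophil markers were higher (3 of 3 measured members at least 2-fold higher and 0 lower, median log2 ratio 2.78, percentile 100). The combined library differed from control by 69 genes higher and 100 lower, and from KRG by 89 higher and 92 lower. Of the 247 genes 2-fold different with BPA, 165 (66.8%) lay closer to control than to BPA in the combined library. Genes that move together are not independent, and no interval is given. The library given KRG without BPA, set in its place, gave 152 (61.5%), and libraries simulated with 1 mean gave 51.1% on average. With total count scaling the median log2 ratio of all genes between these libraries was 0.12, in place of -0.02, which gave 158 genes higher and 89 lower with both, in place of 94 and 117, with 73.2% of BPA genes closer to control.

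**Figure D2:**
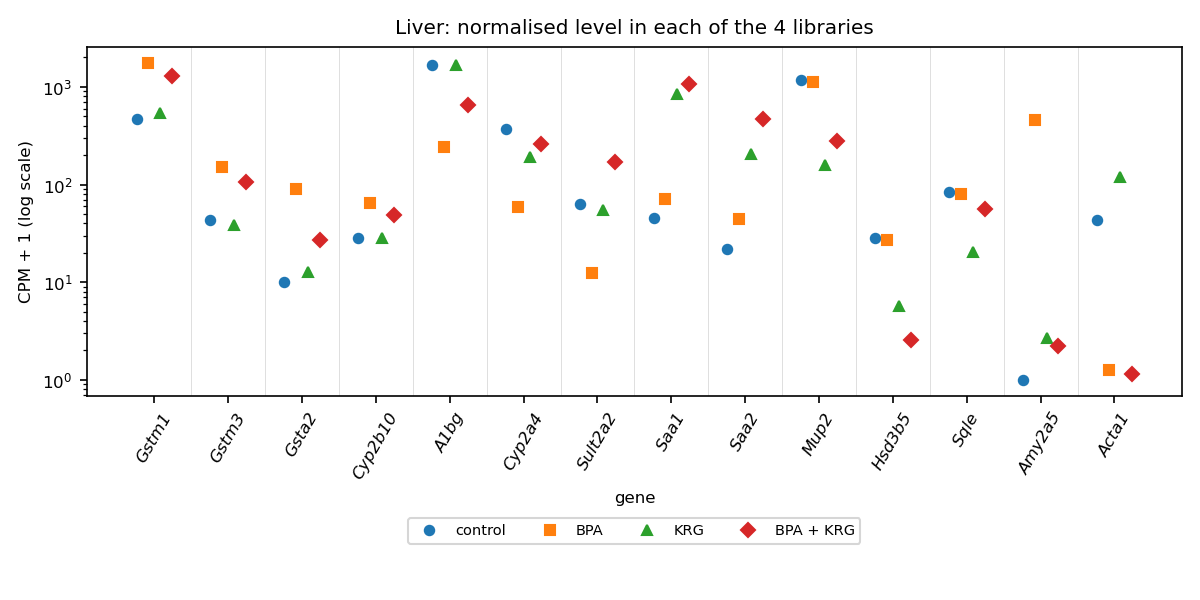
Levels of 14 liver genes in the 4 libraries (CPM + 1 on a log axis, 1 point per library). Gstm1, Gstm3 and Gsta2 are higher in both libraries given BPA, Saa1 and Saa2 are higher and Mup2 and Hsd3b5 lower in both given KRG, and Amy2a5 is high only in the BPA library.

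In uterus, BPA against control gave 255 genes at least 2-fold higher and 170 lower, where simulated libraries with 1 mean gave 232.6 genes 2-fold apart on average. The largest ratios included uroplakins, membrane proteins of the bladder lining. Upk3a stood at 66.3, 1216, 7.57 and 2705 CPM, 18.3-fold (95% counting interval 17.1 to 19.6) higher with BPA. Upk1a stood at 89.3, 1609.9, 46.2 and 3194 CPM, and Upk2, Upk1b, Psca, Krt20, Ivl, Gjb6 and Fmo5 were likewise lowest in KRG and highest in the combined library. The list of bladder and vaginal squamous markers had 4 of 7 measured members at least 2-fold higher and 0 at least 2-fold lower, namely Upk3a, Upk2, Upk1a and Trp63, while Krt14, a keratin of squamous epithelium, stood at 59.3, 31.9, 31.8 and 3.4 CPM. Its median was 1.18, and with a filter of 1 CPM it came inside the middle 95%, at 0.24. Uroplakins also differed between the 2 libraries without BPA, with Upk3a at 66.3 CPM in control and 7.57 in KRG. The NRF2 target list had 4 of 19 measured members at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.25, percentile 99.7), with Nqo1 at 3.58, 31, 5.43 and 58.1 CPM and Slc7a11 at 29.8, 8.94, 14.7 and 6.33 CPM. Sprr2a2 of cornified epithelium stood at 31.1, 439, 2.96 and 728 CPM and the steroid reductase Srd5a1 at 6.29, 56.2, 4.44 and 91.9 CPM. Collagens Col1a1 (268, 668, 671 and 623 CPM) and Col1a2 (429, 1133, 769 and 1117 CPM) were lowest in control, within an extracellular matrix list with 7 of 44 measured members at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.55, percentile 100). The list was lower with both against KRG (median log2 ratio -0.37, percentile 0.01) and higher with KRG against control (0.70). Smooth muscle markers moved with it, with 3 of 14 measured members at least 2-fold higher and 0 lower with BPA (median log2 ratio 0.31, percentile 99.97) and 2 of 14 measured members at least 2-fold higher and 0 lower with KRG (median log2 ratio 0.52, percentile 100). Stromal fibroblast markers had 3 of 14 measured members at least 2-fold higher and 0 lower with BPA (median log2 ratio 0.31, percentile 99.96) and 3 of 14 measured members at least 2-fold higher and 0 lower with KRG (median log2 ratio 0.23, percentile 98.2). With both against KRG the medians were -0.22 for smooth muscle and -0.26 for fibroblasts. The fibroblast median with KRG came inside the middle 95% with a pseudocount of 5 CPM, at 0.21.

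Ltf, lactotransferrin, which estrogen induces in uterine epithelium, stood at 793, 116, 226 and 82.6 CPM, 6.82-fold lower (6.48 to 7.18) with BPA than in control. Ltf is also a neutrophil marker, and that list had 0 of 6 measured members at least 2-fold higher and 2 lower with BPA (median log2 ratio -0.76, percentile 0) and 0 of 6 measured members at least 2-fold higher and 5 lower with both against KRG (median log2 ratio -2.57, percentile 0). Greb1 was at 34.1, 15, 30.1 and 8.09 CPM, the progesterone receptor Pgr at 119, 71.5, 84.3 and 49.6 CPM and Esr1 at 190.2, 145, 159.8 and 89 CPM. The estrogen-induced list had 4 of 25 measured members at least 2-fold higher and 4 at least 2-fold lower (median log2 ratio -0.27, percentile 0.04) and a median of -0.64 with both against KRG. The 4 higher were Sprr2a2, Sprr2a3, Sprr2b and Prap1, and the 4 lower were Ltf, Greb1, Ramp3 and Padi1. The excess over the KRG library was 1.66 times as large in the combined as in the BPA library for Sprr2a2, 1.68 for Sprr2a3 and 1.76 for Sprr2b. These lay within 1.5-fold of the uroplakins' 2.01 (the median of Upk1a, Upk2 and Upk3a), as did Nqo1 (2.06) and Srd5a1 (1.69). Skeletal muscle genes had a median of 1.23 with BPA. Uterine epithelium markers had a median of 0.09 with BPA and 1.05 with both against KRG. Erythroid markers were lower with BPA (0 of 8 measured members at least 2-fold higher and 5 lower, median log2 ratio -1.11, percentile 0). The ribosomal protein list, fixed as a measure of sample quality, had 0 of 60 measured members at least 2-fold higher and 1 lower with BPA (median log2 ratio -0.35, percentile 0) and a median of -0.54 with both against KRG (percentile 0). With BPA the median log2 ratio was 0.24 for macrophage, -0.24 for endothelial and -0.28 for adipocyte markers, none of whose members reached 2-fold, and 0.72 for mesothelium markers, with 1 of 5 measured members at least 2-fold higher and 0 lower. The endothelial median came inside the middle 95% with a filter of 1 CPM (-0.15) and the macrophage median with a pseudocount of 5 CPM (0.21). Hepatocyte genes were lower in both libraries given BPA: Alb stood at 234, 4.57, 434 and 2.11 CPM, Fabp1 at 93, 0.97, 117 and 0.34 CPM and Ahsg at 159, 2.77, 292 and 0.544 CPM (0 of 14 measured members at least 2-fold higher and 14 lower, median log2 ratio -4.43, percentile 0). Of the 115 genes lower in both BPA pairs, 76 had a mean level at least 10-fold higher in liver, against 150 of all 9198 genes tested.

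Over both BPA pairs in uterus 199 genes were higher and 115 lower, against 15.4 and 9.33 for independent lists, and 10 were in opposite directions, against 24.3. Simulated libraries with 1 mean, in which genes were drawn independently of each other, gave at most 7 genes in both pairs. Ratios with and without ginseng had a Pearson correlation across genes of 0.70 and a Spearman correlation of 0.38. The additive model called 97 genes higher and 77 lower by edgeR's quasi-likelihood test and 273 and 146 by DESeq2. Without the genes at least 10-fold higher in liver, 39 genes were lower in both pairs. That setting was added after the data were seen. Of the 199 higher genes, 157 had an excess over the KRG library whose ratio between the combined and BPA libraries lay within 1.5-fold of the uroplakins' 2.01.

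Ginseng alone in uterus gave 268 genes at least 2-fold higher and 110 lower, against 232.6 on average in simulated libraries with 1 mean. With total count scaling, which moved the median log2 ratio of all genes to -0.12, there were 199 higher and 154 lower. Adipocyte genes were higher (9 of 12 measured members at least 2-fold higher and 0 at least 2-fold lower, median log2 ratio 1.78, percentile 100), and had a median of 0.33 with both against BPA. Lpl stood at 826, 716, 3652 and 1021 CPM, 4.42-fold (95% counting interval 4.33 to 4.51) higher with KRG, Cidec at 218, 188, 1236 and 255 CPM and Adipoq at 417 CPM in control and 1559 with KRG. Neutrophil genes were higher as well, with Ngp at 13.7, 21.2, 127 and 22.8 CPM and S100a8 at 194, 93.9, 737 and 105 CPM (4 of 6 measured members at least 2-fold higher and 1 lower, median log2 ratio 1.97, percentile 100), though the members Ltf and Lcn2 were lower. With both against BPA the list had 0 of 6 measured members at least 2-fold higher and 0 lower. Saa1 and Saa2 stood at 92.1 and 88.1 CPM with KRG against 1.17 and 0.292 in control. The cell cycle list had 0 of 20 measured members at least 2-fold higher and 1 lower (median log2 ratio -0.53, percentile 0), Plk1 at 16.1, 28.4, 6.66 and 29.5 CPM and Top2a at 51.5, 64.4, 28.2 and 54.9 CPM, with a median of -0.05 with both against BPA. Uterine epithelium markers had 0 of 17 measured members at least 2-fold higher and 1 lower with KRG (median log2 ratio -0.52, percentile 0). Among the genes lowest with KRG against control, Itln1 stood at 1605, 137, 55.1 and 17.5 CPM, Gp2 at 82.2, 3.81, 1.15 and 0.204 CPM, Muc5b at 448, 29.3, 18.8 and 9.38 CPM, Wfdc18 at 83.9, 4.43, 0.658 and 1.36 CPM and Tff1 at 54.7, 0.416, 0.411 and 0.136 CPM. Itln1 was 29.1-fold lower (27 to 31.5) with KRG than in control. All of these genes were highest in control and were lower with BPA as well, so the difference is not particular to KRG.

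Hepatocyte genes were higher in the KRG uterus than in control (10 of 14 measured members at least 2-fold higher and 0 lower, median log2 ratio 1.29, percentile 100), and had a median of -0.21 with both against BPA. Medians lay below 0 with KRG for bladder and squamous (0 of 7 measured members at least 2-fold higher and 2 lower, median log2 ratio -0.88, percentile 0), mesothelium (0 of 5 measured members at least 2-fold higher and 1 lower, median log2 ratio -0.40, percentile 0.54) and erythroid markers (0 of 8 measured members at least 2-fold higher and 0 lower, median log2 ratio -0.26, percentile 1.28). With a filter of 1 CPM the mesothelium median came inside the middle 95%, at -0.13. Over both KRG pairs 7 genes were higher (Ldb3, Atf3, Stmn1, Gm14403, Rn4.5s, Pnpla3 and Acaa1b) and 16 lower, against 3.67 and 1.97 for independent lists (5 higher and 22 lower with total count scaling), and 22 were in opposite directions, against 6.31. Across genes the correlation was -0.01. The additive model called 0 genes for KRG by edgeR (402 at an unadjusted p under 0.05), and 13 higher and 10 lower by DESeq2.

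Adding ginseng to BPA in uterus gave 126 genes at least 2-fold higher and 165 lower than BPA alone, against 232.6 on average in simulated libraries with 1 mean. Total count scaling gave 96 higher and 200 lower. Skeletal muscle genes were higher, with Pvalb at 0, 3.6, 0.411 and 84.1 CPM, Myh4 at 0.146, 5.2, 0 and 91.5 CPM and Tnnt3 at 1.97, 3.26, 2.22 and 56.5 CPM (10 of 10 measured members at least 2-fold higher and 0 at least 2-fold lower, median log2 ratio 3.25, percentile 100). The interferon response list had 0 of 13 measured members at least 2-fold higher and 4 lower (median log2 ratio -0.72, percentile 0), with Ifit3 at 32.6, 34.2, 9.79 and 11.9 CPM. The circadian clock list had 0 of 16 measured members at least 2-fold higher and 2 lower (median -0.47). Antigen presentation genes of class II had 1 of 5 measured members at least 2-fold higher and 2 lower (median -0.65), the higher one being H2-DMb1 (90, 7.27, 8.47 and 54.8 CPM). Erythroid (0 of 8 measured members at least 2-fold higher and 5 lower, median log2 ratio -1.12, percentile 0) and stromal fibroblast markers (0 of 14 measured members at least 2-fold higher and 1 lower, median log2 ratio -0.27, percentile 0.24) also had medians below 0, as did the ribosomal protein list (0 of 60 measured members at least 2-fold higher and 0 lower, median log2 ratio -0.14, percentile 0.06). The median of bladder and squamous markers lay above 0 (1 of 7 measured members at least 2-fold higher and 1 lower, median log2 ratio 0.62, percentile 99.98), and inside the middle 95% with a filter of 1 CPM (0.21). With KRG against control the medians were -0.16 for muscle, -0.20 for interferon, 0.12 for clock and -0.60 for class II genes. A group of genes on chromosome 4 was lower: Il11ra2 (42656355 to 42661893) stood at 318, 170.4, 426 and 9.72 CPM, 17.5-fold lower (14.8 to 20.9) than with BPA, and Gm13305, Gm13306, Gm2002 and Ccl27b were lower as well. Gm13305 stood at 310.1, 167, 421 and 9.18 CPM, nearly equal to Il11ra2, Ccl27b (42655251 to 42656005), a chemokine gene that does not overlap Il11ra2, at 115, 57.2, 157 and 3.06 CPM and Gm13306 at 118, 56.9, 156 and 2.79 CPM, while Ccl27a on the same chromosome (41769467 to 41774247) was 19.1-fold (95% counting interval 16.2 to 22.7) higher. These are coordinates of the mm10 build.

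The combined uterus library differed from control by 498 genes higher and 313 lower and from KRG by 556 higher and 505 lower. Of the 425 genes 2-fold different with BPA, 39 (9.18%) lay closer to control than to BPA in the combined library, against 345 (81.2%) in the library given KRG without BPA and 49.9% on average in simulated libraries with 1 mean. Bladder lining and hepatocyte genes, which tissue carried into the samples may account for, are among the 425. The share may therefore follow such tissue rather than an effect of BPA. No share without the genes near the uroplakins' ratio is given.

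**Figure D3:**
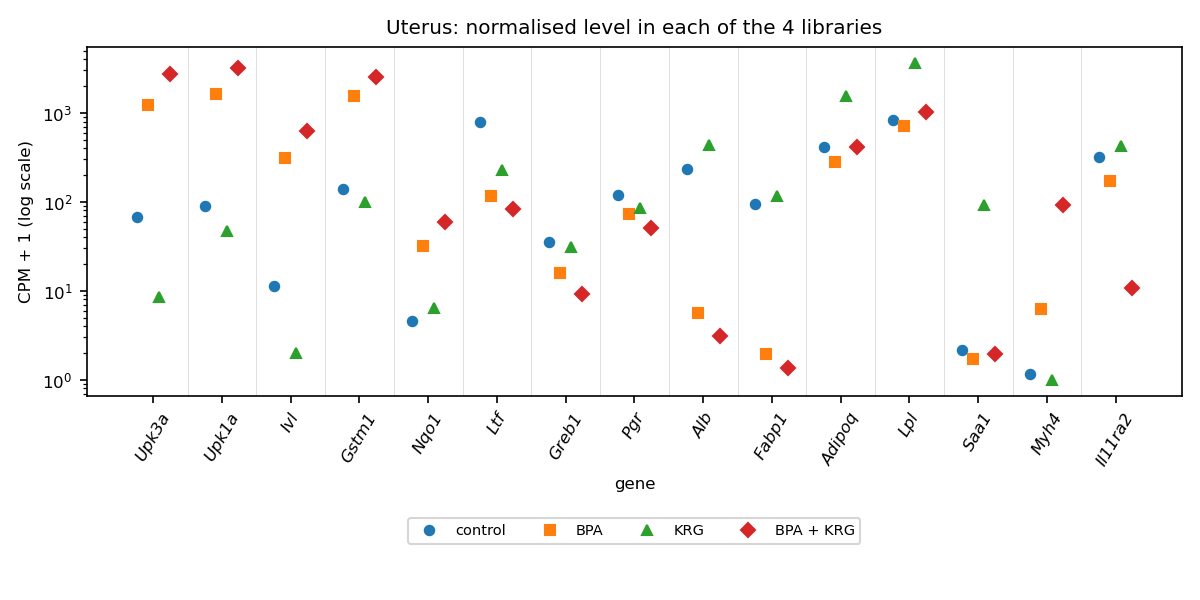
Levels of 15 uterus genes in the 4 libraries (CPM + 1 on a log axis, 1 point per library). Upk3a, Upk1a, Ivl, Gstm1 and Nqo1 are higher and Ltf, Alb and Fabp1 lower in both libraries given BPA, Lpl, Adipoq and Saa1 are highest with KRG, and Il11ra2 is lowest in the combined library.

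Liver and uterus shared few genes. Of 5968 genes measured in both, 4 were higher and 14 lower in both BPA pairs of liver, and 74 and 90 in uterus. Gstm1 was higher in both tissues (0.0496 expected of independent lists), at 139.8, 1528, 98 and 2556 CPM in uterus, and A1bg was lower in both (0.211 expected). In uterus, the excess of Gstm1 over the KRG library was 1.72 times as large in the combined as in the BPA library, near the uroplakins' 2.01. A1bg is at least 10-fold higher in liver than in uterus, and without such genes 1 gene was shared. Ckm, Mylpf, Tnnc2 and Tsku were lower in liver and higher in uterus, where the same ratio was 1.81 for Tsku and 9.66 to 17.7 for the 3 muscle genes. For KRG, Cwc22 was lower in both tissues and 0 genes were higher in both. In uterus Cwc22 was also among the genes at least 2-fold higher in both BPA pairs. Genes named from these overlaps were chosen after their values were seen.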

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

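All tests in this part were chosen after the results they measure had been seen. The bounds for the epithelium share and for the liver fold of Il11ra2 were set when their values were already known, and the test of Gm13306 and Ccl27b took the bounds of Gm13305 and Il11ra2 when the levels of all 4 genes were known.

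Skeletal muscle genes differed with BPA in opposite directions in the 2 tissues, and both pairs of libraries of each tissue gave the same sign for the genes named here. The log2 ratios, given as BPA against control and then both against KRG, were -3.57 and -5.33 in liver and 2.22 and 5.20 in uterus for Ckm, -2.29 and -4.41 in liver and 1.97 and 5.61 in uterus for Mylpf and -5.22 and -6.85 in liver and 1.44 and 6.33 in uterus for Tnnc2, and the median of the skeletal muscle list was -4.29 and -5.83 in liver and 1.23 and 5.17 in uterus. Tsku, a secreted protein not on that list, had -1.31 and -1.28 in liver and 2.28 and 3.10 in uterus. In uterus its excess over the KRG library was 1.81 times as large in the combined as in the BPA library, within 1.5-fold of the uroplakins' 2.01, while the same ratio was 9.66 for Ckm, 13.1 for Mylpf and 17.7 for Tnnc2. The uterus excess of these muscle genes thus lay mostly in the combined library, which is a single library. The difference between tissues was not tested, and no explanation of the muscle genes was tested.

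Bladder lining genes were higher in both uterus libraries given BPA. Of the 199 genes higher in both pairs, 78.9% (157) had an excess over the KRG library whose ratio between the combined and BPA libraries lay within 1.5-fold of the uroplakins' 2.01, the median of Upk1a, Upk2 and Upk3a. Without these and Upk1b (1.56), 153 of 195 did. Beside them stood 31.7% of 2219 other genes, which only had to exceed KRG by 5 CPM in the BPA library and are not a matched set. Both excesses share the KRG library. Bladder lining carried into these samples in different amounts would give this, and an effect of BPA that was stronger in the combined library would too. An equal rise in CPM in both would give a ratio near 1. An equal fold would give a ratio below 1 for uroplakins, which were lower in KRG than in control. The gland markers Foxa2, Cxcl15 and Ltf had a median log2 ratio over both pairs of -1.585. This speaks against a gain of gland epithelium only as far as they follow the amount of gland. Ltf is also a neutrophil marker that estrogen induces, and Cxcl15 was lower in both KRG pairs too. Against a larger share of uterine epithelium stands the median of 17 epithelium markers, 0.57 (range -1.585 to 3.05), where Upk1a, Upk2 and Upk3a had 5.61. Bladder lining in the samples may account for much of the pattern, and an action of BPA on luminal cells was not tested and stays open.

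Hepatocyte genes were lower in both uterus libraries given BPA. Over 252 genes at least 10-fold higher in liver with a mean there of at least 200 CPM, levels in the control uterus followed the control liver with a Spearman rho across genes of 0.772 (0.841 in KRG, 0.307 in BPA and 0.212 in both), at a median of 1.74% of the liver level in control and 4.28% in KRG, against 0.131% and 0.127% in the libraries given BPA. Alb reached 234 CPM in the control uterus and 434 in KRG, and liver tissue or RNA in the uterus samples without BPA may account for the pattern. Carry-over from the liver library of the same treatment would give the KRG to control ratios of liver: the slope across 35 genes was 0.485 (95% interval 0.223 to 0.745 from 2000 resamples of genes), which lies between the bounds set for and against it, so carry-over of that kind cannot be told apart from liver tissue of another source. An effect of BPA on hepatocyte genes in uterus was not tested.

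Il11ra2, Gm13305, Gm13306, Gm2002 and Ccl27b were lower in the uterus library given both. Other genes of that stretch of chromosome 4 were not lower alike: Ccl21a stood at 29.6 CPM with BPA and 30.7 with both, and Ccl21b at 17 and 13.8. Il11ra1 went the other way, at 137, 70.6, 132 and 344 CPM in the uterus libraries. Ccl21a, Ccl21b and Il11ra1 were chosen after their values were seen. The ratio of Gm13305 to Il11ra2 counts varied by no more than 1.05-fold over the 8 libraries, as 1 set of reads counted under both would give, so the pair may be 1 observation. The ratio of Gm13306 to Ccl27b, which stood at lower levels, varied by up to 1.22-fold, between the bounds set for and against shared reads, so shared reads cannot be told apart from separate counts there. An inherited difference between outbred animals cannot be told apart from a treatment effect: Il11ra2 in the combined liver library was 0.454 of the BPA liver library, between the bounds set for either, and each group has 1 library. The bounds could not have decided it, since an inherited difference would reach both tissues if they came from the same animals. In liver Il11ra2 was also low with KRG alone (91.4 CPM, against 204 in control), while in uterus it was highest with KRG (426 CPM). An effect of the combined treatment was not tested.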

How the results depend on the processing

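The alternatives that leave out a set of genes were chosen after seeing the data, and the others before. No paired analysis was possible because each group holds 1 library and the labels give no numbers that link animals. With DESeq2 size factors every count of genes stayed within 1.5 times its value and the share of BPA genes closer to control was 67.2% in liver and 9.22% in uterus. Of the named genes' ratios under other scalings and pseudocounts, 1923 stayed within their counting interval and 433 moved outside it, and no named gene that was at least 2-fold changed sign. Of the printed lists' medians, 736 stayed on the same side of the bounds of the middle 95% of matched lists, 10 came inside and 14 went outside, and no list that lay outside changed sign.

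With a mean of at least 1 CPM more genes entered, and counts grew with them. In liver there were 212 higher and 306 lower for BPA, 170 higher and 149 lower for KRG, 231 higher and 228 lower for both against BPA, 156 higher and 215 lower for both against control, 183 higher and 236 lower for both against KRG, and in uterus 501 higher and 444 lower for BPA, 491 higher and 281 lower for KRG, 284 higher and 348 lower for both against BPA, 933 higher and 725 lower for both against control, 1068 higher and 954 lower for both against KRG. Over both pairs there were 23 higher and 42 lower for BPA in liver, 350 higher and 291 lower for BPA in uterus and 14 higher and 34 lower for KRG in uterus.

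Without an expression filter more genes entered, and counts grew with them. In liver there were 226 higher and 331 lower for BPA, 203 higher and 166 lower for KRG, 266 higher and 247 lower for both against BPA, 177 higher and 237 lower for both against control, 201 higher and 289 lower for both against KRG, and in uterus 528 higher and 490 lower for BPA, 534 higher and 327 lower for KRG, 326 higher and 364 lower for both against BPA, 997 higher and 783 lower for both against control, 1150 higher and 1044 lower for both against KRG. Over both pairs there were 23 higher and 44 lower for BPA in liver, 361 higher and 306 lower for BPA in uterus and 14 higher and 34 lower for KRG in uterus. The share of uterus BPA genes closer to control became 12.9%.

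With total count scaling, liver had 158 genes higher with both than with BPA, and 73.2% of BPA genes closer to control. A pseudocount of 0.25 CPM gave 12 uterus genes higher in both KRG pairs. With a pseudocount of 5 CPM, 7 liver genes were higher in both BPA pairs, 61 uterus genes were lower with KRG, 95 were lower with both than with BPA, 8 were lower in both KRG pairs, 6.44% of uterus BPA genes lay closer to control and 0 genes were shared by the tissues for KRG. The larger pseudocount shrinks the ratio of low genes by construction. The additive model with edgeR called 0 higher and 0 lower for BPA in liver, and 0 and 0 for KRG in either tissue, with 97 higher for BPA in uterus. With DESeq2 it called 13 higher and 10 lower for KRG in uterus. The cause of these differences was not tested. Without genes at least 10-fold higher in the other tissue, 92 uterus genes were lower with BPA, 39 were lower in both BPA pairs, and 1 gene was shared by the tissues for BPA. Leaving out cell type marker genes left all of these counts within 1.5 times. At these depths 3 counts correspond to between 0.192 and 0.247 CPM, so a gene at 0 is not shown to be absent.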

Other observations

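Lpin1 and Bcl6 in liver were high in the BPA and KRG libraries and low in control and in the library given both. They and Ddit4 and Cyp8b1 were chosen after their values were seen. Lpin1 stood at 114, 387, 509 and 82.5 CPM in the order control, BPA, KRG and both, and Bcl6 at 12.5, 46.5, 58.9 and 4.73 CPM. Ddit4 was at 10.9, 72.1, 52 and 39.6 CPM, lowest in control alone, and Cyp8b1, the enzyme that sets the share of cholic acid, at 43.6, 209.8, 55.1 and 31 CPM, high with BPA alone. Cyp26a1, which breaks down retinoic acid, stood at 40.4, 1.97, 4.4 and 22.2 CPM, and the cyclin Ccnd1 at 353, 53, 81.4 and 117 CPM, highest in control.

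Some genes, H2-K1 and Vcp among them chosen after their values were seen, stood at very different levels in single libraries. H2-K1 in liver was at 137, 572, 1057 and 507 CPM, Gm4788 in liver at 1.41, 66.9, 43.4 and 40.6 CPM, H2-DMb1 in uterus at 90, 7.27, 8.47 and 54.8 CPM and the ribosomal protein gene Rplp1 in uterus at 7553, 1778, 2193 and 1862 CPM. On chromosome 4, Vcp (42979963 to 43000507), near the Il11ra2 cluster, stood at 158, 149.5, 276 and 299.9 CPM in liver and 119, 152, 138 and 547 CPM in uterus, and Ccl27a at 10.4, 10.5, 46.5 and 53 and 22.1, 10.2, 25 and 194 CPM, and both were highest in the library of each tissue in which Il11ra2 was lowest (204, 186, 91.4 and 84.6 CPM in liver). Il11ra1, also chosen after its values were seen, was likewise highest in those libraries. It stood at 88, 104, 127 and 131 CPM in liver and 137, 70.6, 132 and 344 CPM in uterus. No explanation of these values was tested.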
